A study of Mus musculus with 43 samples.

How the data were processed

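RNA was taken from 8 tissues of C57BL/6 mice that lacked MDA5, and editing sites were read by multiplex microfluidic PCR followed by sequencing, per the labels' protocols. The 43 libraries were grouped by the genotype in the labels: 9 wild-type (Adar1 +/+), 18 heterozygous (E861A/+) and 16 homozygous (E861A/E861A) libraries. Brain had 2 wild-type, 4 heterozygous and 2 homozygous libraries, and each other tissue had 1, 2 and 2. The labels do not say which libraries came from the same animal, so every p-value treats libraries as independent and may be too small. The age labels increase by a constant step from one sample to the next in list order, so age was not used. The labels R1 and R2 on some brain libraries are not explained in the sources used here.

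Each deposited file lists 48715 sites with chromosome, position, gene, strand and annotation, and gives for each site the coverage and the edited reads as counts, which the authors deposited without normalization. The third value, the editing level, is deposited as a fraction, and it equals edited reads divided by coverage after rounding. Reads were aligned with STAR 2.4.2a to mm9, per the submitters' processing notes. How sites were chosen, how reads at a site were counted, and how duplicate reads and base qualities were treated are not given in the sources used here. Coordinates and annotations below are those of the deposited files on mm9, and none was converted. The reads carry no molecular identifiers in these files, so confidence intervals and detection limits cover counting error only.

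Of the listed sites, 37561 had no read in any library and 10779 had at least 50 reads in at least 1 library. Read depth depends on the amplification of chosen segments and was not used as a measure of expression. A library's level at a site was used where its coverage was at least 50 reads. At 50 reads a level of 10% has a 95% Wilson interval of 4.35% to 21.4%, and a count of 0 allows a level of up to 6%, taking 3 reads as the limit. At the typical coverage of 2089 reads that interval is 8.79% to 11.4%, and a count of 0 allows up to 0.144%.

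The comparisons over all tissues used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16 in R 4.3.3) on edited and unedited read counts. The model had a term for each library, and tissue and genotype terms on the edited counts, and the libraries of all tissues shared the estimate of spread, except the first homozygous spleen library, which had no usable level. A site was tested where at least 3 libraries of each genotype had 50 reads and the mean level over those libraries was at least 1%. A site was called at an adjusted p under 0.05 with a difference of at least 5 percentage points. Levels and differences are means over tissues with each tissue weighted equally, and the standard deviation (SD) is that of the difference between tissues. The common dispersion was estimated from 200 evenly spaced sites (0.306). Comparisons within a tissue and the test of whether the genotype effect differs between tissues used the same test with 1 coefficient per tissue and genotype. Within a tissue at least 2 homozygous and 2 heterozygous libraries with 50 reads were required. Brain was compared with the other tissues over the 27 wild-type and heterozygous libraries with genotype as a covariate. For the heterozygous against wild-type comparison in brain, the requirement of at least 2 heterozygous and 1 wild-type library was set when the fit was written, as was the 1% minimum level for the brain and tissue-difference tests.

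The mean editing level of a library was taken over the 1734 sites with 50 reads in most libraries and a mean level of at least 1%, and was compared with two-sided permutation tests within tissues, exact where all arrangements could be listed. A library lacking 50 reads at some of these sites was given the mean of all site means, plus its mean departure from the site means at the sites it covered. The share of the wild-type level that remained in homozygotes was computed at sites with a wild-type level of at least 5%. A ratio of at least 50% is called kept and one under 10% is called lost. Gene lists and annotation classes were compared with all other tested sites by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. The lists were glutamate receptor subunits, other neuronal recoding genes, widely expressed recoding genes, substrates of ADAR2, genes with edited inverted repeats in the 3' UTR, and each annotation class. Sites of one gene are not independent, so each list was also tested with 1 site per gene. A site with under 5% in both genotypes cannot reach a 5-point difference, so each list was also tested on the sites that could.

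The main tests, the lists, the thresholds and the rule for named sites were fixed before the data were examined. The rule names, for each list, the site with the highest wild-type level and the one with the largest difference. It further names the 10 largest falls, the 5 largest rises and the 5 highest levels in homozygotes, and the 5 largest differences in heterozygotes. It also takes the 2 largest differences within each tissue, the 5 sites highest and the 5 lowest in brain, and the 3 sites with the smallest p for a difference between tissues. At most 1 site per gene, or per 1000 bp where no gene is given, was taken in each group. Other settings fixed in advance were other coverage and level minimums, limma 3.58.1 on arcsine square-root levels, quasi-binomial logistic regression, and leaving out each tissue or each replicate. A replicate block in brain, other thresholds, heterozygotes as the reference and 1 site per gene were also fixed in advance. Chosen after seeing the data were fits without the 2 shallow libraries, fits without the second heterozygous bone marrow library, the spleen comparison with its 1 deep homozygous library, the unblocked fit of the brain wild-type and heterozygous libraries alone, the list tests on sites that could be called, and 2 alternatives for the mean level (sites in all deep libraries, and leaving out tissues).

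The tests were tried on simulated data with the real coverage, first with beta-binomial noise and, after few sites were recovered, also with logit-normal noise; the largest of the simulated effects was added later still. For homozygous against wild type over 1901 simulated sites, an odds ratio of 1/4 gave an adjusted p under 0.05 at 69% of changed sites with logit-normal noise and at 16% with beta-binomial noise, and the full call at 22% and 7%. An odds ratio of 1/16 reached an adjusted p under 0.05 at 94% and 71%. At unchanged sites these shares were 0.5% and 0.143%. Within brain an odds ratio of 1/4 was called at 23.3% of changed sites (1696 sites in the fit) and 0% (1588 sites), and in liver at 11.3% (1273 sites) and 0% (1140 sites). An effect of 1/16 present in brain alone was found by the tissue-difference test at 16% and 0% of changed sites (1901 sites in each fit). For brain against other tissues an odds ratio of 4 was called at 46% (1870 sites) and 1.03% (1685 sites). Under beta-binomial noise the fitted change was overstated: for a log2 odds ratio of -2 the median fitted value was -2.94 over all tissues. A low count of called sites therefore does not show that levels did not differ. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9.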

Results

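Adenosine-to-inosine editing was read at 48715 listed sites in RNA from 8 mouse tissues by multiplex microfluidic PCR sequencing, in which chosen transcript segments are amplified and sequenced deeply. ADAR1 converts adenosine to inosine in double-stranded RNA, and sequencing reads the inosine as guanosine. The E861A allele encodes an ADAR1 protein without editing activity, and all mice lacked MDA5, a cytosolic sensor of double-stranded RNA. Positions are those of the files, on mm9. The set held 9 wild-type, 18 heterozygous and 16 homozygous libraries from bone marrow, brain, heart, kidney, liver, ovary, spleen and thymus. Wild type had 2 libraries in brain and 1 in each other tissue, so a wild-type value within those other tissues has no replicate. Of the 43 libraries, 41 held 19335618 to 33173399 reads over the sites (median 26824848), with 9663 to 10626 sites at 50 reads or more and a median coverage of 1543 to 2583 reads at those sites. The other 2 were shallow. The first homozygous spleen library held 38854 reads and reached 50 reads at 0 sites, so it entered no comparison over sites. The first wild-type brain library held 146448 reads and reached 50 reads at 808 sites.

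The question the series poses is how much editing depends on ADAR1 activity. Mean editing was lower in homozygous than in wild-type libraries in 8 of 8 tissues. Averaged over tissues and over 1734 sites, the level was 8.57% in wild type (n = 9), 5.91% in heterozygotes (n = 18) and 3.39% in homozygotes (n = 15). The shallow wild-type brain library had a value at only 100 of these sites, and without the 2 shallow libraries the means, over 1814 sites, were 8.64%, 6.03% and 3.5%. The homozygous level as a percentage of wild type was 16.6% in bone marrow, 18% in spleen, 19.9% in thymus, 30.7% in liver, 35.6% in kidney, 51.9% in heart, 56.2% in ovary and 69.7% in brain. Brain had the highest level in each genotype, with 12.4% ± 0.344 (SD, n = 4) in heterozygotes and 9.55% ± 0.225 (n = 2) in homozygotes. Brain wild type had 14.2% in its deep library. The shallow library's 13.2% is an adjusted value: the mean of all site means over the 1734 sites, plus its mean departure from the site means at its 100 sites. The mean of both libraries, 13.7%, used above, rests on unlike sets of sites and gives no spread between replicates. The homozygous mean fell by 5.18 percentage points from wild type (SD 1.72 over 8 tissues, exact permutation p = 0.000114, the smallest that the arrangements allow). The heterozygous mean fell by 2.67 points from wild type (SD 1.25, lower in 8 of 8 tissues, exact permutation p = 3.05e-05, also the smallest possible). Between homozygotes and heterozygotes the mean fell by 2.52 points (SD 1.2, 8 of 8 tissues, permutation p = 1e-05, the smallest that 100000 resamples give). With Benjamini-Hochberg adjustment over these 3 comparisons the values were 0.000114, 4.58e-05 and 3e-05. The second heterozygous bone marrow library stood at 1.33%, against 3.67% in the first and 0.870% and 1.17% in the homozygotes of that tissue.

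**Figure D1:**
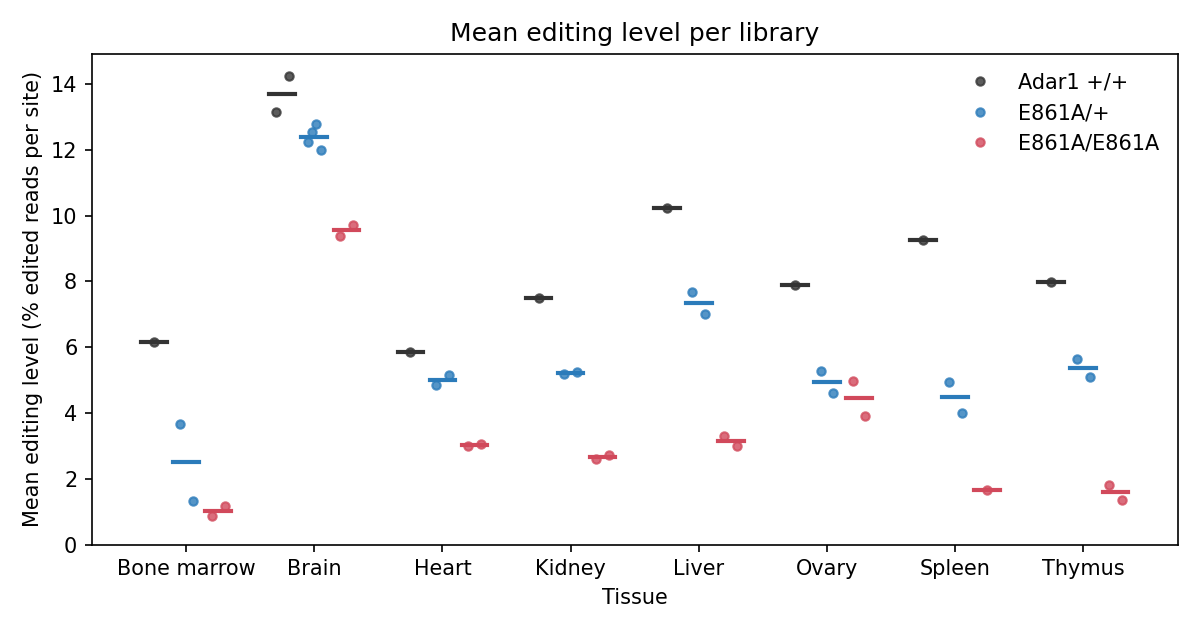
Mean editing level per library (percent edited reads per site, vertical axis) by tissue (horizontal axis) and genotype, where each point is 1 library and each bar is the group's mean. In each of the 8 tissues the homozygous mean lies below the heterozygous mean, which lies below the wild-type level, and the brain means span 9.55% to 13.7%.

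In homozygotes editing fell to a few percent or less at many sites in 3' untranslated regions (UTRs) and intergenic loci. The site with the largest fall lay in the 3' UTR of Mad2l1, a spindle checkpoint gene (chromosome 6, position 66490075), at 74.3% in wild type and 0.913% in homozygotes. It fell by 73.4 points (SD 14.9 over 8 tissues, lower in 8 of 8, adjusted p = 1.55e-12). Adjusted p-values for single sites here and below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The noncoding transcript uc007vsb.1 (chromosome 15, 55087127) stood at 52.5% and 0.491% (lower in 8 of 8 tissues, adjusted p = 5.54e-14). The 3' UTR site of Mdc1, a mediator of the DNA damage checkpoint (chromosome 17, 35994679), stood at 53.0% and 3.65% (7 of 7 tissues, adjusted p = 2.14e-05). The 3' UTR of Slfn5, of the Schlafen family (chromosome 11, 82776122), went from 48.9% to 1.24% (8 of 8, adjusted p = 2.55e-10). The 3' UTR of Car5b, a mitochondrial carbonic anhydrase (chromosome X, 160415964), went from 45.4% to 0.699% (8 of 8, adjusted p = 6.34e-14). Further 3' UTR falls among the 10 largest were in Agphd1 (chromosome 9, 54795019, 49.96% to 2.66%, lower in 7 of 8 tissues), uc008obr.1 (chromosome 2, 169896924, 44.7% to 0.756%) and Ovca2 (chromosome 11, 74989846, 51.7% to 9.35%), with adjusted p = 1.07e-06, 3.57e-08 and 1.82e-07. The other 2 were intergenic, at chromosome 12, 55773344 (44.6% to 0.297%, adjusted p = 2.12e-11) and chromosome 3, 100272400 (44.1% to 0.288%, adjusted p = 2.22e-21).

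Of 1901 sites tested between homozygotes and wild type, 484 were called lower and 5 higher. The lower sites lay in 138 genes or intergenic loci, with a median difference of -11.6 percentage points. The rises lay in 4 genes or loci: uc008dkz.1 (3' UTR, chromosome 17, 70943428, 5.85% to 21.4%, higher in 7 of 8 tissues, adjusted p = 0.0176), Son, a splicing cofactor (a silent proline codon, chromosome 16, 91655832, 1.45% to 8.32%, 7 of 8, adjusted p = 0.0435), Homer1, a postsynaptic scaffold (intron, chromosome 13, 94128152, 14.6% to 21%, 7 of 8, adjusted p = 0.027) and Cyfip2. The remaining site was a second one of uc008dkz.1 (70943434, 1.61% to 13.1%, 6 of 8, adjusted p = 0.00583), outside the rule and named after its values were seen. These calls were weak. Son was not called with limma (adjusted p = 0.183) or with quasi-binomial regression (0.145), nor in 7 other settings (adjusted p 0.0502 to 0.132). Homer1 lost its call in 9 settings (0.052 to 0.0872) and uc008dkz.1 without kidney (0.0832). At 884 sites the adjusted p alone was under 0.05.

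Sites in genes of neuronal signalling and in substrates of ADAR2, the second active editing enzyme, were seldom called between homozygotes and wild type, which alone does not show that their levels were equal. The Gln-to-Arg site of Gria2, which sets calcium permeability of AMPA receptors (chromosome 3, 80510834), stood at 99.5% in wild type and 99.4% in homozygotes (difference SD 0.144 over 7 tissues, adjusted p = 0.581). The other sites with the highest levels in homozygotes were the Arg-to-Gly site of Gria4 (chromosome 9, 4456006, 65.5% and 82.4%, SD 38.4, adjusted p = 0.797), the Gln-to-Arg site of the kainate receptor gene Grik2 (chromosome 10, 48964136, 55.8% and 60.0%, SD 28.2, adjusted p = 0.742), the 5' UTR of uc007fvm.2 (chromosome 10, 76785352, 62.7% and 61.6%, adjusted p = 0.784) and the noncoding uc012aji.1 (chromosome 17, 6122636, 64.7% and 55.2%, adjusted p = 0.34). Single libraries set much of some differences: without spleen, where the only wild-type library had 3.14%, Gria4 stood at 75.9% and 79.5%, and the difference at uc012aji.1 was -5.06 points. Without bone marrow the Grik2 site was called higher, at 12.5 points (adjusted p = 0.0133), and without thymus its difference was -2.22.

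Glutamate receptor subunits had 19 tested sites in 5 genes (Gria2, Gria3, Gria4, Grik1, Grik2), of which edgeR called 0, limma called 0 and 0 had an unadjusted p under 0.05; the count adjusted over the list alone was 0. The share of called sites was lower than elsewhere (Fisher's exact test, adjusted p = 0.0124), and with 1 site per gene the adjusted p was 0.252. Only 10 of the 19 had 5% or more in either genotype and could be called (adjusted p = 0.000784 among such sites, an alternative chosen after seeing the data). Other neuronal recoding genes had 13 sites in 7 genes with 0 calls by edgeR, 0 by limma, 1 unadjusted p under 0.05, and 0 adjusted over the list alone (Fisher's exact adjusted p = 0.0364, 0.24 with 1 site per gene, and 0.00268 over the 8 that could be called). The brain Htr2c site described below had no test over all tissues and is not among them. Among them the Ile-to-Met site of Gabra3, a GABA receptor subunit (chromosome X, 69690631), stood at 34.9% and 36.2%, and the Ile-to-Val site of the potassium channel gene Kcna1 (chromosome 6, 126592176) at 21.9% and 12.5% (SD 26.2, adjusted p = 0.68). Most of the Kcna1 difference came from the only liver wild-type library, at 96.8%, and without liver the levels were 11.2% and 11%. ADAR2 substrates had 21 sites in 5 genes, with 0 lower and 1 higher by edgeR, the same counts adjusted over the list alone, and a Fisher's exact adjusted p of 0.0351 (0.722 with 1 site per gene, and 0.00268 over the 12 that could be called). All 5 genes also belong to the lists of glutamate receptor subunits, other neuronal or widely expressed recoding genes, so this list is not separate evidence. The higher site was the Lys-to-Glu site of Cyfip2, a subunit of the WAVE actin regulatory complex (chromosome 11, 46086145), at 17.2% and 22.3% (SD 7.58, higher in 8 of 8 tissues, adjusted p = 0.00153). Its difference dropped below the 5-point minimum without brain (4.54), liver (2.75), ovary (4.62) or the libraries labelled R2 (4.54).

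Widely expressed recoding genes had 15 sites in 7 genes, with 1 lower and 1 higher, both over all sites and adjusted over the list alone (Fisher's exact adjusted p = 0.415). The lower one was the Tyr-to-Cys site of Blcap (chromosome 2, 157383885), at 7.95% and 1.59% (SD 5.39, lower in 8 of 8 tissues, adjusted p = 0.000128), and the higher one was that of Cyfip2. The Ile-to-Val site of Cog3, a Golgi tethering subunit (chromosome 14, 76119526), stood at 42.5% and 43.4% (SD 5.46, adjusted p = 0.935). Azin1, Cdk13, Igfbp7 and Ube2o had no tested site. Genes with edited inverted repeats in the 3' UTR had 48 tested sites, all in Mad2l1 and Cds2, of which 32 were called lower and 0 higher (0 higher with limma as well), and 33 were lower when adjusted over the list alone. Called sites were more frequent than elsewhere (odds ratio 6.1, Fisher's exact adjusted p = 7.32e-09), and with 1 site for each of these 2 genes the adjusted p was 0.24. Klf1, Optn, Oip5 and Slc7a2 had no tested site.

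A call needs a difference of at least 5 points, so 1003 of the 1901 sites, with under 5% in both genotypes, could not be called; each class was tested again on the other 898 as an alternative chosen after seeing the data. By annotation, 3' UTR sites were called most often, with 400 lower and 2 higher of 1293 (odds ratio 2.7, Fisher's exact adjusted p = 9.7e-15, 7.58e-07 with 1 site per gene, and 4.82e-14 over sites that could be called). Intronic sites were called less often than others, with 20 lower and 1 higher of 225 (odds ratio 0.266, adjusted p = 7.02e-10, 0.000654 with 1 site per gene, and 1.44e-07 over the 83 that could be called). Coding sites that change an amino acid had 2 lower and 1 higher of 61 (odds ratio 0.144, adjusted p = 0.000107, 0.00328 with 1 site per gene, and 0.000159 over the 23 that could be called). Silent coding sites had 0 lower and 1 higher of 21 (adjusted p = 0.0351, 0.252 with 1 site per gene, and 0.201 over the 5 that could be called). In 5' UTRs edgeR called 0 of 19 sites and limma 0, with 2 at an unadjusted p under 0.05 (Fisher's exact adjusted p = 0.0124, 0.24 with 1 site per gene, and 0.00527 over the 7 that could be called). Intergenic sites had 45 lower of 189 (adjusted p = 0.599, and 0.909 over the 84 that could be called) and noncoding RNA 17 lower of 93 (adjusted p = 0.136, 0.311 with 1 site per gene, and 0.000784, with fewer calls than elsewhere, over the 55 that could be called, which lie in only 7 genes or loci). Adjusted over the list alone, the lower counts were 403 for 3' UTR, 18 for intronic, 2 for amino acid changing, 0 for silent and 5' UTR, 45 for intergenic and 17 for noncoding sites. The highest wild-type level among 3' UTR sites was in Rpa1, a subunit of the single-stranded DNA-binding replication protein A (chromosome 11, 75114517), at 76.6% and 43.2% in homozygotes (SD 34.7, lower in 7 of 8 tissues, adjusted p = 0.00122). Among intronic sites it was in Adarb1, the gene of ADAR2 (chromosome 10, 76786805), at 45.7% and 50.1% (adjusted p = 0.485), with a difference of 2.06 points without bone marrow. The largest intronic difference was in Atp11b (chromosome 3, 35706977), at 37% and 2.58% (SD 50.7, lower in 3 of 5 tissues, adjusted p = 0.0238); it was not called with quasi-binomial regression (0.089) or without brain, ovary, thymus or the libraries labelled R2 (0.0695 to 0.218). Without ovary, where the only wild-type library had 99.8%, the Atp11b difference was -18.1. Of the silent coding sites, that of Gria2 (chromosome 3, 80510830) had the highest wild-type level at 21.2%, with 27.6% in homozygotes, and the Leu site of Son (chromosome 16, 91656378) had the largest difference, at 16.1% and 5.04% (adjusted p = 0.535 and 0.77). The Son value rests on 1 wild-type brain library at 99.7%: without brain the levels were 4.2% and 3.66%. That of Gria2 differed by 1.07 points without spleen and 13.7 without liver. The largest difference in a 5' UTR was in uc007fvm.2 (chromosome 10, 76785366), at 45.7% and 55% (adjusted p = 0.681), and differed by 2.06 points without ovary.

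At sites with at least 5% in wild type, homozygotes kept at least 50% of the wild-type level at 271 sites (31.5%), fell under 10% of it at 304 (35.3%), and lay between at 286. The median homozygous level was 20% of wild type. Levels were kept at 24.6% of 626 sites in 3' UTRs, 21.2% of 80 intergenic sites, 52.8% of 53 noncoding RNA sites, 64.4% of 73 intronic sites and 84.2% of 19 amino acid changing sites. Levels were lost at 39.9%, 37.5%, 18.9%, 17.8% and 5.26% of these, in the same order. With heterozygotes in place of wild type as the reference, 48.1% of sites were kept and 22.9% lost.

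**Figure D2:**
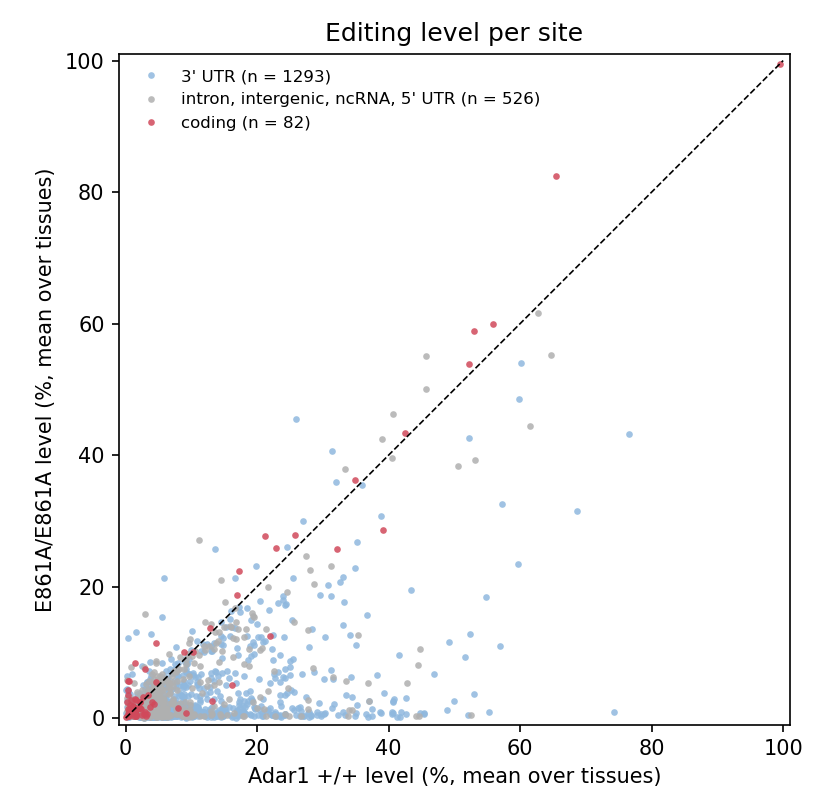
Editing level per site in wild type (horizontal axis, percent) and in homozygotes (vertical axis, percent), each a mean over tissues, with points coloured by annotation and a dashed line of equal levels. Some coding sites lie near the line, such as Gria2 at 99.5% and 99.4%, and others off it, such as Gria4 at 65.5% and 82.4% and Blcap at 7.95% and 1.59%, while many 3' UTR sites lie along the bottom, such as Mad2l1 at 74.3% and 0.913%.

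Heterozygotes, which carry 1 working allele, were compared with wild type to see whether editing depends on the number of working copies. The 3' UTR of Calcrl, the calcitonin receptor-like receptor gene (chromosome 2, 84172932), stood at 40.4% in wild type and 12.6% in heterozygotes, and fell by 27.9 points (SD 12.6, lower in 8 of 8 tissues, adjusted p = 0.000987). The 3' UTR site of Mdc1 (chromosome 17, 35994679) stood at 53.0% and 16% (SD 23.6, lower in 6 of 7 tissues, adjusted p = 0.0203). The 3' UTR of Coq3, a methyltransferase of coenzyme Q synthesis (chromosome 4, 21838814), stood at 34.2% and 9.35% (SD 30.6, 7 of 8, adjusted p = 0.0304). The intergenic sites at chromosome 3, 100272400 (44.1% and 21.3%, SD 5.28, 8 of 8, adjusted p = 0.00015) and chromosome 12, 55773344 (44.6% and 20.02%, SD 16.3, 8 of 8, adjusted p = 0.0199) fell too. Of 1901 sites, edgeR called 107 lower in 55 genes or loci, and 0 higher, while 17 higher sites had an unadjusted p under 0.05; limma called 0 higher and quasi-binomial regression 5. The number of calls depended on the setting, with 251 by limma, 306 by quasi-binomial regression, 61 without bone marrow and 55 without spleen. Mdc1 lost its call without bone marrow, kidney, liver or ovary (adjusted p 0.0501 to 0.0712), Coq3 with no minimum level or without any of 5 tissues (0.0527 to 0.121; its difference was -15 points without spleen, where the only wild-type library had 98.7%), and the chromosome 12 site without bone marrow (0.0528).

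Homozygotes and heterozygotes have 2 or more usable libraries in each tissue but spleen, which has 1 homozygous library, so the loss of the last working copy was tested in 7 tissues one by one. Over all tissues 247 of 1901 sites were called lower in homozygotes and 6 higher, in 91 and 5 genes or loci. The Mad2l1 site at 66490075 was among the 2 largest differences in 6 of the 7 tissues tested. It stood at 84.7% ± 0.522 in heterozygous and 0.178% ± 0.135 in homozygous liver (adjusted p = 2.48e-07), and at 67.6% ± 2.83 and 0.0800% ± 0.113 in thymus (adjusted p = 1.82e-07), with n = 2 in each group. In bone marrow it stood at 69.3% and 0.231%, in kidney at 58.7% and 0.554%, in ovary at 57.2% and 3.35% and in heart at 49.6% and 0.285%. In liver the 3' UTR of Rnf168, a ubiquitin ligase of DNA repair (chromosome 16, 32299939), stood at 82.6% ± 4.77 and 0.337% ± 0.0102 (adjusted p = 1.18e-05), and wild type had 50.3%. In thymus the 3' UTR of Rragd, a Rag GTPase (chromosome 4, 33107392), stood at 67.1% ± 1.32 and 0.782% ± 0.0649 (adjusted p = 3.3e-05). In kidney uc008obr.1 (169896924) stood at 60.3% ± 4.02 and at 0% in homozygotes, where the count of 0 allows up to 0.686% in each library (adjusted p = 0.000598).

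In brain the Ile-to-Val site of Htr2c, a serotonin receptor gene (chromosome X, 143604229), stood at 78.9% ± 11.8 (n = 4) in heterozygotes and 0.514% ± 0.43 (n = 2) in homozygotes, with 82.9% in wild type (adjusted p = 0.00294, and 0.0562 without the first homozygous library). An intergenic brain site at chromosome 6, 31465667, stood at 80.1% ± 8.11 and 3.22% ± 2.67 (adjusted p = 0.000136). In heart the 3' UTR of 2900026A02Rik (chromosome 5, 113517035) stood at 43.4% ± 18.1 in heterozygotes and 0.254% in homozygotes, but the wild-type library had 0.226% (adjusted p = 0.0179); without any 1 of the 4 libraries the adjusted p was 0.0545 to 0.104. Both of the other named sites were higher in homozygotes: the 5' UTR of uc007fvm.2 (chromosome 10, 76785366) in bone marrow at 83.3% ± 23.6 against 0% in heterozygotes, where the count of 0 allows up to 2.73% in each library (adjusted p = 0.00101), and the noncoding uc011ynq.1 (chromosome 12, 74010371) in ovary at 38.1% ± 36.7 against 1.14% ± 0.516 (adjusted p = 0.0415). The uc011ynq.1 difference was 11 points without the first homozygous ovary library (adjusted p = 0.326), and its adjusted p was 0.121 and 0.189 without either heterozygous one.

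Lower and higher calls within a tissue were 337 and 11 of 1539 sites in thymus, 276 and 12 of 1553 in liver, 174 and 2 of 1447 in kidney, 103 and 1 of 1406 in heart, 101 and 10 of 1129 in bone marrow, 99 and 4 of 2317 in brain and 54 and 6 of 1646 in ovary. In spleen, tested with its 1 deep homozygous library as a comparison chosen after seeing the data, they were 228 and 31 of 1498. That lone library is assumed to vary like the other groups. The bone marrow total was 238 without its second heterozygous library and 71 without the first. The higher counts depended on single libraries: leaving out 1 library gave 12 to 48 in liver, 2 to 16 in kidney, 2 to 8 in heart, 8 to 44 in bone marrow, 3 to 11 in brain, 1 to 13 in ovary and 8 to 21 in thymus. The brain total was 65 without its first homozygous library, and the ovary total was 39 and 40 without either heterozygous library. At sites with at least 5% in heterozygotes, homozygotes kept at least 50% of the level at 73.8% of 1086 brain sites and 69.5% of 443 ovary sites. In heart the share was 43.8% of 452, in kidney 31.8% of 466, in liver 24.4% of 533, in spleen 13.3% of 390, in thymus 12.2% of 534 and in bone marrow 9.9% of 202.

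Whether the homozygous effect differs between tissues was tested directly. The 3' UTR site of Rpa1 at 75114095 (chromosome 11) stood at 36.9% ± 0.185 in heterozygous and 0.452% ± 0.119 in homozygous bone marrow, at 38.6% ± 1.13 and 0.522% ± 0.169 in thymus, but at 21% ± 1.48 and 9.59% ± 2.37 in brain (adjusted p for a difference between tissues = 5.03e-07). Ankrd28, a regulatory subunit of protein phosphatase 6 (3' UTR, chromosome 14, 32513849), stood at 47% and 2.08% in liver and at 6.73% and 3.76% in brain (adjusted p = 1.57e-05). Mad2l1 at 66490203 (3' UTR, chromosome 6) stood at 29.1% and 0.143% in bone marrow and at 15.4% and 8.14% in brain (adjusted p = 2.58e-05). In total 184 of 1880 sites in 71 genes or loci differed between tissues by edgeR's quasi-likelihood test. Limma gave 374, and edgeR without the second heterozygous bone marrow library gave 284.

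The tissues were also compared with each other where ADAR1 activity was present. The question was which sites are edited more or less in brain. The Ile-to-Met site of Gabra3 stood at 92.8% in brain and 24.1% elsewhere (SD 12.6 over 7 tissues, adjusted p = 2.88e-11). The Tyr-to-Cys site of Grik2 (chromosome 10, 48992582) stood at 87.2% in brain and 0.313% elsewhere, where only an ovary and a thymus library had 50 reads (adjusted p = 0.000569); without the libraries labelled R2 it was not called (adjusted p = 1). Further sites high in brain were the 3' UTR of 3830431G21Rik (chromosome 12, 81824736, 92.5% and 7.73% over 6 other tissues, adjusted p = 1.59e-05), the silent Leu site of Son (76.6% and 7.11%, adjusted p = 0.000611, although heterozygous brain had 68.9% ± 53.5, n = 3) and an intergenic site at chromosome 11, 95932957 (70.9% and 5.6%, adjusted p = 2.04e-08). Lower in brain were the 3' UTR sites of Mad2l1 at 66490075 (28.4% and 69.9%, adjusted p = 2.18e-08), uc008obr.1 (9.23% and 44.8%, adjusted p = 0.00835), Rnf168 (5.72% and 33.6%, adjusted p = 0.00119) and Pfas, an enzyme of purine synthesis (chromosome 11, 68799439, 2.4% and 26.8%, adjusted p = 1.13e-09). The Ile-to-Val site of Htr2c at 143604241 (chromosome X) was lower in brain too (60.4%, against 88.7% with SD 19.3 over only 3 other tissues, adjusted p = 0.0024, and 0.0613 with limma). The call of uc008obr.1 was lost without the libraries labelled R2 (adjusted p = 0.104). The brain mean of Rnf168 pools unlike libraries and describes neither genotype, because heterozygous brain alone, given in a later part, stood far below it. Of 2082 sites, 763 were called higher in brain and 74 lower. Among wild-type libraries alone limma called 39 of the 118 sites that could be tested, 35 higher and 4 lower.

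Within brain, where wild type has 2 libraries, 12 of 2347 sites were called lower in heterozygotes than in wild type and 0 higher by edgeR's quasi-likelihood test, with 132 sites at an unadjusted p under 0.05, 47 of them higher. The median difference at the lower sites was -8.1 points. Limma called 101 lower and 7 higher. Nearly all of the wild-type reads came from the second library, without which 142 sites could be tested and 0 were called. These 12 calls used an estimate of spread shared with the other tissues. The brain wild-type and heterozygous libraries fitted alone gave 0 of 2436 sites, both with the R1 and R2 labels as a block (150 at an unadjusted p under 0.05) and without it (226), the latter fit being chosen after seeing the data.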

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

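Chosen after the result was seen were the test of 1 working copy in heterozygotes, both tests of the second heterozygous bone marrow library, and, for the first homozygous spleen library, the use of sites high in brain against its own homozygous RNA and the comparison with brain homozygotes. The other tests in this part were chosen before.

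Editing in heterozygotes lay below wild type in 8 of 8 tissues, at 5.91% against 8.57%. A shift of whole libraries at all sites would lower every site by the same factor. Sites were classed from the other tissues as kept or lost in homozygotes (here at least 80% or under 10% of a heterozygous level of at least 5%). The log2 ratio of heterozygous to wild-type level at kept minus lost sites averaged 0.524 (SD 0.303, above 0 in 8 of 8 tissues). The two-sided exact sign-flip p was 0.00781, the smallest possible, which argues against such a shift as the whole cause. A shift as part of the cause stays open, because kept sites also stood below wild type in most tissues. They stood at 59.7% of it in bone marrow, 67.5% in spleen, 80.1% in liver, 81.3% in thymus, 89.6% in ovary and 97.4% in brain. In heart and kidney they stood at 109% and 106%. Lost sites stood little lower than kept sites in liver (73.5%) and thymus (74%). At lost sites the fall from wild type to heterozygotes was 41.2% of the fall to homozygotes (SD 15.2 over 8 tissues). This share was not corrected for the fall at kept sites. Both this share and the bone marrow ratio above include the second heterozygous bone marrow library, and neither was computed without it. At lost sites that library stood at 15.6% of wild type, against 67.6% in the first. Hence 1 working copy of Adar1 may limit editing at lost sites, as a hypothesis found on the same data, with the wild-type libraries shared by both falls. A difference between the wild-type and heterozygous animals other than the allele cannot be told apart from it, because 0 tissues have 2 deep wild-type libraries.

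The second heterozygous bone marrow library had a mean level of 1.33%, against 3.67% in the first. Few starting molecules would scatter levels up and down, but its summed level was 37.3% of the first library's (95% bootstrap interval over 325 genes or loci 28.2% to 47%), which argues against them. A wholly homozygous library under a heterozygous label is argued against: at lost sites it stood at 15.6% of the bone marrow wild-type level (95% bootstrap interval over 58 genes or loci 7.6% to 23.1%), against 1.81% and 2.12% in the bone marrow homozygotes and 67.6% in the first heterozygous library. It was above both homozygotes at 79 of 130 lost sites, in 44 genes or loci (63.5% against 0.22% and 0.241% at Mad2l1 66490075), but not at the other 51, and it was close to them at Calcrl (0.57% against 0.452% and 0.562%); only brain homozygotes, from another tissue, reached a higher share (18.4%). A mix with homozygous RNA was not tested, and no biological explanation was tested.

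The first homozygous spleen library, which entered no comparison, had 2.44% of its 38854 reads edited, against 2.38% in wild-type spleen and 0.640% in the other homozygous spleen library. Its own homozygous spleen RNA is argued against: at lost sites 2.01% of its reads were edited (95% Wilson interval 1.13% to 3.57%), whose lower bound does not pass the highest homozygous library at 1.14%, so the test chosen before leaves it open, but at sites high in brain and low in wild-type spleen it had 61.0% (50 of 82 reads), against 1.88% in the other homozygous spleen library. A spleen library with working ADAR1 is argued against by the lower bound of that value, 50.2%, against 12.8% in heterozygous spleen. The 1.28% in wild-type spleen is no test, because these sites were chosen for a low level there. That bound treats the 82 reads, from 24 sites in 16 genes or loci, as independent. An even mix of reads from all other libraries would give 20.4% there and was not met, while an uneven mix stays open and cannot be told apart. Ranked by the likelihood of its edited reads over 7375 sites, a brain homozygous library came first (rank 1 of 41) and the deep spleen homozygote came 36, so reads of a brain homozygous library are a candidate source, and no biological explanation was tested.

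The effect of the homozygous genotype differed between tissues at 184 sites. The test of the difference gave adjusted p = 5.03e-07 for Rpa1 at 75114095, 1.57e-05 for Ankrd28 and 2.58e-05 for Mad2l1 at 66490203, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment as for the next sites. Pfas went from 38.5% in heterozygous to 0.454% in homozygous thymus and from 2.26% to 0.582% in brain (adjusted p for the difference 0.000169). Ovca2 stood at 52.8% and 1.48% in thymus and at 52.9% and 39.8% in brain (0.000239). Rnf168 stood at 82.6% and 0.337% in liver and at 0.177% and 3.65% in brain (0.000919). With so low a heterozygous level, a fall in brain could not show at Rnf168. Mad2l1 at 66490075 stood at 84.7% and 0.178% in liver and at 24% and 2.25% in brain (0.00266). The Arg-to-Gly site of Gria4 stood at 99.8% and 87.1% in thymus and at 91.4% and 90.7% in brain (0.00293). Rragd stood at 67.1% and 0.782% in thymus and at 1.48% and 0.732% in heart (0.0105). The intergenic site at chromosome 6, 31465667, stood at 80.1% and 3.22% in brain and at 4.51% and 3.72% in thymus (0.0423).

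Among the 4 heterozygous brain libraries, 1 stood apart from the others at an intronic site of Adarb1 (76786805), where the gap was 0.857 of the whole range around a mean of 79.0% ± 0.614. At the silent proline site of Son (91655832) the gap was 0.996 of the range around a mean of 19.4% ± 38.5. These are 2 of 44 groups tested, and chance gives about 1 in 20.

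Genotype labels permuted within tissues gave as many called sites in 1 of 32 splits, the real one included, for each of the 3 genotype comparisons. That argues against chance but does not exclude it, because 1 of 32 is the smallest share possible. Libraries were permuted as independent, although some may come from the same animal. All 3 genotype labels were permuted together, so homozygous libraries entered the other groups. That mixing can widen the spread and lower the counts in the heterozygous against wild-type splits. The real counts were 489, 107 and 253 for homozygous against wild type, heterozygous against wild type and homozygous against heterozygous, and the highest of the other splits gave 195, 0 and 0. For brain against other tissues 1 of 32 splits, the real one, gave as many as its 837 sites, and the highest other gave 0. In these splits the labels of all tissues were permuted together, so each permuted group mixed tissues. That mixing can widen the spread and lower the counts, so the 0 is no measure of how far brain differs from the other tissues.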

How the results depend on the processing

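Chosen after seeing the data were the fits without the 2 shallow libraries, without the second heterozygous bone marrow library, and of the brain wild-type and heterozygous libraries alone without a block, the list tests over sites that could be called (5% or more in wild type or homozygotes), and the mean levels without each tissue or over sites in all deep libraries. No called result changed sign. Homozygous minus wild-type differences not called in either setting did so at 9 points: Gabra3 without liver (-0.43) or ovary (-0.0512), Cog3 at 20 reads (-0.0618) or without heart (-0.229), uc007fvm.2 76785352 without kidney (0.329) and 76785366 at 200 reads (-6.35), Grik2 48964136 without thymus (-2.22), and uc011ynq.1 (-3.62) and 3830431G21Rik (-4.36) without ovary. The intergenic class with 1 site per gene (adjusted p = 0.37) went from fewer to more calls than elsewhere, past no threshold. Of the alternatives run on comparisons, 189 left direction, threshold side or size as they were (a count within 1.5 times), 27 moved the value, 7 ended a call and 1 made one; on named sites 1033 left the call, 50 ended one and 7 made one. The differences in mean level were -6.37 to -4.73, -3.33 to -2.24 and -3.04 to -2.2 points for homozygous against wild type, heterozygous against wild type and homozygous against heterozygous. Where the alternative does not itself change the number of sites or the threshold, the cause was not tested.

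For those same 3 comparisons the adjusted p alone gave 884, 255 and 676 sites, and a 10-point minimum 276, 45 and 131. A mean level of at least 5% left 322 sites for homozygous and 58 for heterozygous against wild type, with fewer sites tested. Heterozygous against wild type gave 68 with no minimum level, 251 with limma, 306 with quasi-binomial regression, 61 without bone marrow and 55 without spleen. Within tissues, leaving out 1 replicate gave 71 to 238 sites in bone marrow, 65 to 99 in brain and 39 to 46 in ovary, and limma gave 179 in brain. Heterozygous against wild type in brain gave 108 with limma and 0 to 15 leaving out 1 replicate. The R1 and R2 labels do not show that libraries are paired; with them as a replicate block edgeR gave 0 sites (150 of 2436 at an unadjusted p under 0.05), and the same 6 libraries without the block also gave 0 (226). The test of a difference between tissues gave 374 sites with limma and 284 without the second heterozygous bone marrow library. Brain against other tissues in wild type alone with limma gave 39. With heterozygotes as the reference 48.1% of sites were kept and 22.9% lost. With 1 site per gene the Fisher's exact adjusted p was 0.252 for glutamate receptors and silent sites, 0.24 for other neuronal genes, inverted repeats and 5' UTRs, and 0.722 for ADAR2 substrates, with fewer sites per list. Over sites that could be called it was 0.201 for silent sites and 0.000784 for noncoding RNA (fewer calls than elsewhere), where 1 site per gene gave 0.311. The mean level over sites covered in all libraries could not be computed, because the first homozygous spleen library has no site at 50 reads. At 50 reads a level under 6% can be missed, and the 2 shallow libraries have few or no such sites.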

Other observations

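Within some genes or loci, sites differed in how much editing remained in homozygotes. Whether this was more or less frequent than a random assignment of sites to genes would give was not tested. This tally of genes and the test of annotation classes below were chosen after the values were seen. Of 221 genes or loci with a site of at least 5% in wild type, 135 had 2 or more such sites. In 39 of these at least 1 site was kept and at least 1 was lost, in 14 all sites were lost and in 21 all were kept. Slfn5 lost all of its 11 sites, which lie within 91 bp, and Car5b lost all 8 within 105 bp. Adarb1 kept all 6 of its sites within 37 bp, at 80.4% to 109% of the wild-type level, and Grik2 kept all 4 of its sites, at 107% to 145%. In Rpa1, of 21 sites within 482 bp 9 were kept and 2 were lost, with ratios from 2.09% to 99.1%. Mad2l1 had 28 sites within 775 bp, of which 19 were lost and 1 was kept. The gene 3830431G21Rik had 19 sites, of which 16 were kept and 1 was lost, and uc012fou.1 kept 9 of its 11 sites and lost 0, with ratios of 46.3% to 111%.

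The share of kept sites differed between annotation classes. It was higher for amino acid changing sites (16 of 19 kept, odds ratio 12.2, two-sided Fisher's exact adjusted p = 5.65e-06), intronic sites (47 of 73, odds ratio 4.54, adjusted p = 5.56e-09), noncoding RNA sites (28 of 53, odds ratio 2.6, adjusted p = 0.00157) and 5' UTR sites (7 of 7, adjusted p = 0.000508), and lower for 3' UTR sites (154 of 626, odds ratio 0.33, adjusted p = 3.17e-11) than for all other sites. Sites of one gene are not independent, and these tests count sites.

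The shallow wild-type brain library had 2.21% of its reads edited, and its edited reads over 7056 sites were closest in likelihood to the second wild-type brain library (rank 1 of 41).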
